A study of Arabidopsis thaliana with 18 samples.

How the data were processed

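RNA sequencing measured polyadenylated transcripts of Arabidopsis thaliana plants of the Col-0 accession grown in hydroponic medium. Plants of 6 weeks were exposed for 72 h to 5 µM lanthanum (La) or 5 µM ytterbium (Yb), both given as chlorides, or were not exposed. The medium lacked phosphate in every group, the control included. Roots and shoots were taken apart, 3 plants were pooled for each replicate, and each of the 6 groups of tissue and treatment held 3 replicates, which gave 18 libraries. The labels do not say whether the replicates of a group grew in separate containers, and they give no batch, date or lane.

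Per the labels, the libraries were stranded and paired-end, and the authors' processing notes list Trimmomatic 0.36.1, TopHat2 2.1.1, HTSeq 0.6.1p1 and the genome build TAIR10. The role of each tool and the strand setting of the counting are not given in the sources used here. The deposited values are a signal per gene: read counts divided by a single size factor per library, although the tables carry the name of a unit that also divides by gene length. All values of each library (100%) were whole multiples of a single step within 0.001, whatever the length of the gene, and the steps equalled the inverse of median-of-ratios size factors computed within the 9 libraries of each tissue. The analysis had been planned for length-normalized values, so the unit differed from what the plan assumed. The planned test on log2 values was kept, and count-based tests on the recovered whole reads were added after the data had been examined. Because each table was normalized within its tissue, differences between roots and shoots were computed only as differences of effects within each table.

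The recovered totals were 12.8 to 16.22 M reads per library in roots and 12.44 to 16.35 M in shoots. Size factors were 0.9015 to 1.1446 in roots and 0.8775 to 1.1662 in shoots. Replicates differed by more than counting error: the chi-square per degree of freedom between replicate libraries was 7.65 to 23.32 in roots and 3.24 to 12.61 in shoots. Intervals and floors from read counts therefore cover counting error only.

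Each table held 28991 genes. Gene names and neighbours came from a copy of the TAIR10 annotation, in which 28781 genes were matched by locus; the other 210 comprised 88 chloroplast and 122 mitochondrial genes. That copy's build may differ from the authors' and was used for names and neighbours only. All 422 members of 26 gene lists were found in the tables. The lists were fixed before the data were examined. Among them, photosynthesis and light harvesting marked green tissue in root libraries, root hair growth and Casparian strip and suberin marked root tissue in shoot libraries, floral organs and bolting marked inflorescence tissue, and circadian clock marked harvest time.

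Genes were tested when at least 3 libraries of the tissue had a value of at least 1. Values were transformed as log2(value + 0.5) and fitted with limma 3.58.1 in R 4.3.3, with treatment group as the single factor, over the 9 libraries of a tissue. Empirical Bayes moderation used a trend and was robust. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The contrasts were La against control, Yb against control and La against Yb, in roots and in shoots. Fold changes are fitted log2 differences on this scale, given with their SE. For a gene at 0 in all libraries of a group, the fold is a lower bound computed against a floor of 3 counts per library. No fold is given when both groups lie under the floor, and bounds were recomputed without each library in turn. The difference in effect between tissues was tested by a fit of all 18 libraries on the genes tested in both tissues.

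Gene lists with at least 5 tested members were tested with camera (limma) with a preset inter-gene correlation of 0.01, and adjusted over the lists of a contrast. The same test with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, were the alternatives. A member is said to have risen or fallen when its adjusted p over all genes tested was below the threshold; the count adjusted over the list alone is given beside it. Genes past the threshold for both elements in the same direction were counted against the overlap of independent lists and against simulated treated groups with no change that shared the same controls, since 3 control libraries cannot be divided into equal sets.

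The rule for named genes took, for each contrast, the 6 largest rises and 6 largest falls among genes past the threshold with a mean value of at least 1 and groups that did not overlap, the 3 members with the smallest adjusted p of the 6 lists with most members past the threshold, and a panel of 8 genes: IRT1, BHLH38, FER1, SPX1, PHT1;4, ALMT1, ZIP9 and APR3. The difference between tissues was given for genes named in a contrast against the control in either tissue and tested in both. Other members of the lists, and other genes, that are named in the text were chosen after their values were seen.

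Alternatives set before the data were examined were pseudocounts of 0.1 and 1, no filter, a minimum value of 5, rescaling by median ratios, equal library totals, quantile normalization, moderation that was not robust, library weights, the 6 compared libraries alone, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Added after the data had been examined were edgeR 4.0.16 with a quasi-likelihood test, the Wald test of DESeq2 1.42.0, a minimum value of 10, and, for the gene lists, leaving out each library, also in their difference between tissues, and the 3 scalings. The deposited values already carry median-of-ratios factors, so rescaling by median ratios could move nothing and is no test. Other splits of the libraries were counted for each result.

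The test of La against control was tried on counts simulated from the means and spread of each tissue, with 22868 genes tested in roots and 21995 in shoots. Changed genes were drawn only from genes above a minimum mean, so recovery among genes with few reads was not measured. Noise was drawn for each gene on its own, without shifts that the genes of a library share. In roots limma recovered 38.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 98.5% of those changed 4-fold, with 10 false calls among 147. In shoots it recovered 62.7%, 82.1% and 95.5%, with 10 false calls among 170. DESeq2 made 30 false calls among 181 in roots and 19 among 182 in shoots. For the 85 named genes, near-identical copies were searched with BLAST+ 2.17.0 at 90% identity over 60% of the transcript, limits that were lowered after stricter ones had found none. The search left out 1 of them, ATMG00030, which was not in the annotation copy, so its copies and overlaps are unknown. A near-identical copy was found for 8 genes, an overlapping gene on the same strand for 2 and on the opposite strand for 17. Reads shared between such genes, and the strand on which reads were counted, could not be examined in tables of counts, so their values carry that uncertainty. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample or column was left out.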

Results

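The data are normalised read counts per gene from 18 RNA sequencing libraries of Arabidopsis roots and shoots, 9 libraries per tissue. In each tissue 3 libraries came from plants exposed to the light rare earth element La, 3 from plants exposed to the heavy rare earth element Yb and 3 from plants not exposed, all in medium without phosphate. Root libraries held 12.8 to 16.22 M reads and shoot libraries 12.44 to 16.35 M. The series asks how the transcripts of roots and shoots respond to these elements. Every mean below is over 3 replicates, in reads per size factor, with its SD, and every log2 fold change has its SE. The p-values measure the spread between samples only, since the labels do not say whether replicates grew in separate containers.

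In the roots, the first principal component held 62.8% of the variance of the log2 values and set the La libraries (37.2 to 70.1) apart from the controls (-41.9 to -38.7). Libraries Yb 1 and Yb 2 lay between them at 2.7 and 5.6, while library Yb 3 lay at -37.6, beside the controls. The second root component held 13.6%, with the Yb libraries (-29.5 to -7.8) apart from the controls (12.8 to 19.9) and La 1, La 2 and La 3 at -13.4, 14.9 and 12.7. In the shoots the first component held 31.5%. The controls (-8.4 to 27.7) overlapped both the La libraries (-3.4 to 14.2) and the Yb libraries (-21.7 to -4), while every Yb library lay below every La library. The second held 19% and set the La libraries (-14 to -10.9) apart from the controls (8.6 to 16.7), with Yb 1, Yb 2 and Yb 3 at 7.7, -3.4 and -1.7.

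In roots exposed to La, IMA1 (AT1G47400), which encodes a short peptide that promotes iron uptake, went from 19.61 ± 7.74 to 159.6 ± 21.5, a log2 fold change of 3.07 ± 0.28 (adjusted p = 0.000433). RSL2 (AT4G33880), a transcription factor of root hair growth, went from 375.7 ± 109 to 35.08 ± 30.8, a log2 fold change of -3.83 ± 0.75 (adjusted p = 0.0127). Of 22729 genes tested, 4300 changed, 2139 up and 2161 down, and 1797 of them had at least a doubling or halving. Of the changed genes 4278 had groups that did not overlap; over all tested genes the share with no overlap was 37.5%, where chance gives 10%. The count fell to 2588 without library La 2 and to 2698 without control 3.

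Of the 27 measured members of the iron deficiency list, 18 rose in La roots, 1 fell and 8 did not pass the test (20 up and 1 down adjusted over the list alone). The median member changed by 1.07 on the log2 scale (adjusted p = 7.31e-12 for the list, and adjusted p = 0.157 with an estimated correlation). OPT3 (AT4G16370), a phloem transporter of iron, rose by 2.15 ± 0.20 (adjusted p = 0.000433), and the ferric reductase FRO3 (AT1G23020) by 1.08 ± 0.11 (adjusted p = 0.000578). IRT1 (AT4G19690), the main iron transporter of the root surface, rose from 2945 ± 681 to 7495 ± 2067, by 1.34 ± 0.23 (adjusted p = 0.00556). The transcription factor BHLH38 (AT3G56970) rose 7.14-fold, by 2.84 ± 0.41 (adjusted p = 0.0038). The member that fell was FIT (AT2G28160), the transcription factor that drives IRT1, with -0.79 ± 0.13 (adjusted p = 0.00378). Of the 9 measured members of the iron storage list, 3 fell and 6 did not pass (0 up and 3 down adjusted over the list alone), with a list median of -0.32 (adjusted p = 0.0177, and adjusted p = 0.231 with an estimated correlation). Those that fell were the ferritins FER1 (AT5G01600, -0.90 ± 0.17) and FER3 (AT3G56090, -1.13 ± 0.12) and the transporter YSL1 (AT4G24120, -1.31 ± 0.40). The storage list had adjusted p = 0.0771 without La 2.

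**Figure D1:**
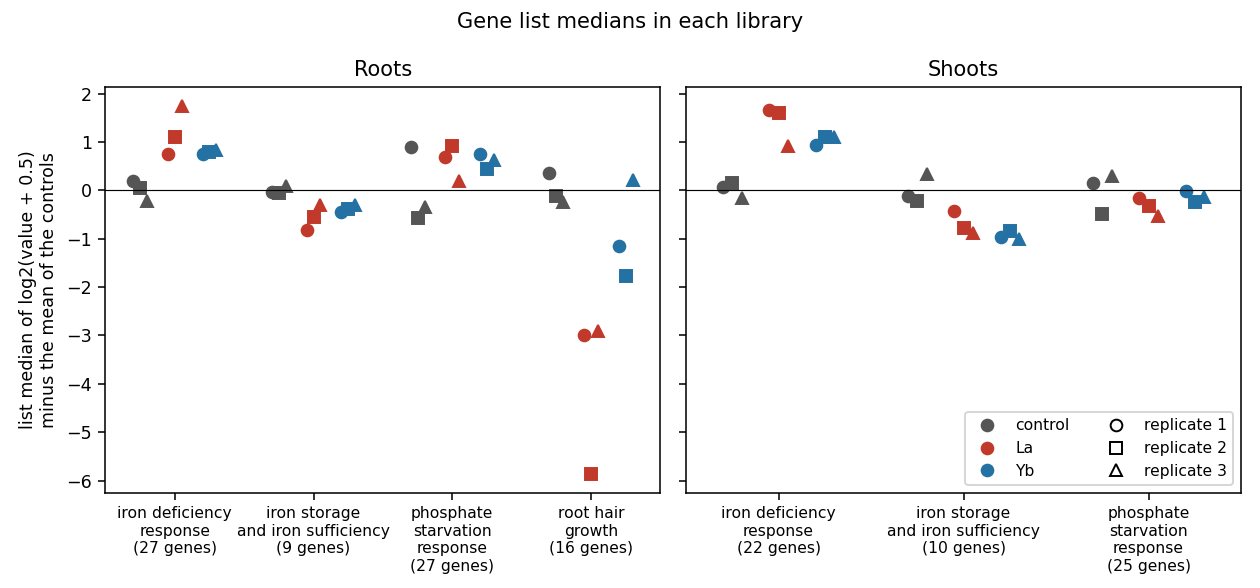
Each point is 1 library: the median over a gene list of log2(value + 0.5), less the mean of the control libraries, for 4 lists in roots and 3 in shoots, coloured by treatment with a marker per replicate. The iron deficiency medians of all 12 exposed libraries (0.76 or higher in roots, 0.91 or higher in shoots) lie above those of the controls (0.2 or lower in roots, 0.15 or lower in shoots), while the root hair median of Yb 3 (0.22) lies among the controls.

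Of the 16 root hair genes, 12 fell in La roots and 4 did not pass (0 up and 13 down adjusted over the list alone). The list median was -3.94 (adjusted p = 1.27e-08, and adjusted p = 0.335 with an estimated correlation). AGP3 (AT4G40090), an arabinogalactan protein gene, fell by 4.21 ± 0.80, and the peroxidase gene RHS19 (AT5G67400) had -4.33 ± 0.83. The expansin EXPA7 (AT1G12560), which loosens hair walls, had -4.94 ± 0.99. The list of Casparian strip and suberin genes, which build the barriers of the endodermis, moved in both directions: of 16 members 7 rose, 6 fell and 3 did not pass in La roots (8 up and 7 down adjusted over the list alone). The list as a whole was not called (adjusted p = 0.647), with a median of 0.09 and a mean of -0.52. Among the members that rose were the fatty acid elongase gene KCS2 (AT1G04220, 0.92 ± 0.13, adjusted p = 0.0023), the fatty acid hydroxylase gene CYP86A1 (AT5G58860, 1.12 ± 0.17, adjusted p = 0.00297) and the fatty acid reductase gene FAR5 (AT3G44550, 1.03 ± 0.17, adjusted p = 0.00373). Among those that fell were the membrane scaffold genes CASP4 (AT5G06200, -3.72 ± 0.75, adjusted p = 0.014) and CASP1 (AT2G36100, -2.00 ± 0.51, adjusted p = 0.0345), and ESB1 (AT2G28670, -1.63 ± 0.35, adjusted p = 0.0178).

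**Figure D2:**
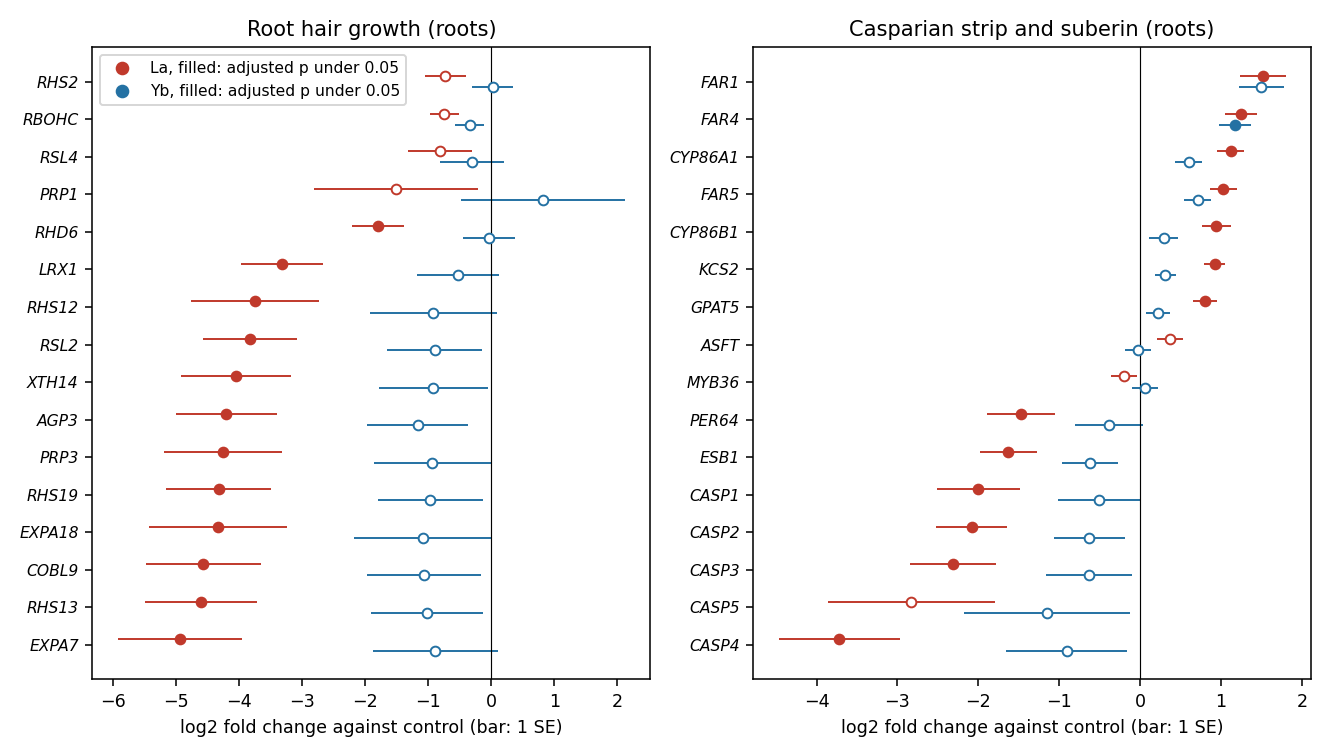
Log2 fold changes against control in roots, with bars of 1 SE, for La and Yb, of the 16 members of the root hair list and the 16 members of the Casparian strip and suberin list; filled points have an adjusted p below 0.05. With La, 12 root hair genes fell, while 7 members of the other list rose, 6 fell and 3 did not pass.

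Of 11 measured members of the senescence and sugar starvation list 7 rose and 4 did not pass in La roots (8 up and 0 down adjusted over the list alone). The list median was 0.78 (adjusted p = 1.1e-05, and adjusted p = 0.157 with an estimated correlation). The transcription factors NAC2 (AT5G39610) and NAP (AT1G69490) rose by 2.80 ± 0.20 and 2.02 ± 0.16, and NYC1 (AT4G13250), a chlorophyll b reductase, by 2.63 ± 0.27. Of 18 oxidative stress and detoxification genes 11 rose, 1 fell and 6 did not pass (11 up and 1 down adjusted over the list alone). Their median was 0.63 (adjusted p = 1.1e-05, and adjusted p = 0.125 with an estimated correlation). They include the glutathione transferase GSTU24 (AT1G17170, 1.49 ± 0.16), the zinc finger factor ZAT12 (AT5G59820, 1.31 ± 0.14) and the NADPH oxidase RBOHD (AT5G47910, 0.74 ± 0.10), while the catalase CAT2 (AT4G35090) fell by 0.56 ± 0.11.

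Of 17 abscisic acid and water deficit genes 5 rose, 1 fell and 11 did not pass in La roots (8 up and 1 down adjusted over the list alone). They had a median of 1.09 (adjusted p = 0.000233, and adjusted p = 0.368 with an estimated correlation). HAI1 (AT5G59220), a phosphatase of abscisic acid signalling, rose by 1.47 ± 0.17. Of 15 ethylene genes 4 rose and 11 did not pass (5 up and 0 down adjusted over the list alone). The list had adjusted p = 0.0177, and adjusted p = 0.57 with an estimated correlation. The ethylene synthesis gene ACS7 (AT4G26200) rose by 2.84 ± 0.38. The ethylene call was lost without control 1 (adjusted p = 0.0563), control 3 (0.0773) or La 3 (0.0651). In the phosphate starvation list, 1 of 27 members rose, the ribonuclease RNS1 (AT2G02990, 3.61 ± 0.71), and 26 did not pass (1 up and 0 down adjusted over the list alone). The phosphate list was called with a median of 0.61 (adjusted p = 0.0211, and adjusted p = 0.819 with an estimated correlation), but not without control 2 (0.276), control 3 (0.176), La 1 (0.0625) or La 2 (0.17). Its median was 0.90 in control 1, at the level of exposed libraries, against -0.58 in control 2 and -0.35 in control 3. SPX1 (AT5G20150), a phosphate sensor, and the phosphate transporter PHT1;4 (AT2G38940) had 0.61 ± 0.37 and 0.71 ± 0.43 (adjusted p = 0.305 and 0.303).

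The zinc list split in La roots, with 4 of 15 members up, 6 down and 5 not past the test (4 up and 6 down adjusted over the list alone; adjusted p = 0.646 for the list). The zinc transporter ZIP2 (AT5G59520) rose 3.39-fold, by 1.76 ± 0.24, whereas ZIP9 (AT4G33020) fell by 1.12 ± 0.31. ZIP10 (AT1G31260) and the metal transporter MTP2 (AT3G61940) were at 0 in all 3 La libraries, at least 4.86-fold and at least 5.07-fold lower than in the controls (adjusted p = 0.0034 and 0.00765). Without control 2 the bound of MTP2 was 2.78-fold. The root malate channel ALMT1 (AT1G08430), known from aluminium tolerance, rose by 1.66 ± 0.48 (adjusted p = 0.0487), and APR3 (AT4G21990), an enzyme of sulfate reduction, by 0.40 ± 0.12 (adjusted p = 0.0446).

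XTH11 (AT3G48580), a cell wall enzyme gene, was at 0 in all controls and at 130.7 ± 52.7 in La roots, at least 41.7-fold higher (adjusted p = 0.000643). The phosphatase gene 5PTASE11 (AT1G47510) went from 1.37 ± 2.37 to 114.5 ± 9.34, AT4G05540 from 2.469 ± 1.28 to 312.8 ± 64.7, and AT5G56368, AT1G51020 and AT1G51000 rose by 5.65 or more. The largest falls were in AT5G46900, from 2276 ± 217 to 3.39 ± 3.19, AT5G46890, from 1924 ± 243 to 2.978 ± 1.83, AT4G12510 (-8.54 ± 1.13), AT5G33355 (-8.26 ± 1.93), AT4G12520 (-7.13 ± 1.07) and AT4G22217 (-6.74 ± 0.88). AT5G46900 and AT5G46890 are near-identical copies of each other, as are AT4G12510 and AT4G12520, and AT1G51020 has such a copy, so reads of 1 copy can have been counted for the other. Of 36 named genes called in La roots, 29 kept their call without each of the 6 libraries in turn. Calls were lost without La 1 (4), La 2 (7), La 3 (3), control 1 (5), control 2 (7) and control 3 (4).

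Some of the iron signalling and senescence genes that rose in La roots also rose in Yb roots, with fewer genes past the threshold. IMA1 (AT1G47400) rose by 2.87 ± 0.28 to 139.5 ± 20.9 (adjusted p = 0.0064), its relative IMA2 (AT1G47395) by 2.84 ± 0.42 (adjusted p = 0.0283) and OPT3 (AT4G16370) by 1.71 ± 0.20 (adjusted p = 0.00968). Of the 27 iron deficiency genes 4 rose and 23 did not pass. Adjusted over the list alone 17 rose and 1 fell, and the list median was 0.58 (adjusted p = 1.29e-12, and adjusted p = 0.286 with an estimated correlation). IRT1 (AT4G19690) had 0.36 ± 0.23 (adjusted p = 0.475), BHLH38 (AT3G56970) 1.67 ± 0.41 (adjusted p = 0.105) and FER1 (AT5G01600) -0.66 ± 0.17 (adjusted p = 0.0986). The 9 iron storage genes did not pass singly (0 up and 2 down adjusted over the list alone) and had a median of -0.44 (adjusted p = 0.0216, and adjusted p = 0.313 with an estimated correlation). Of the 11 senescence genes 3 rose and 8 did not pass (5 up and 0 down adjusted over the list alone). The list had adjusted p = 6.45e-05, and adjusted p = 0.286 with an estimated correlation. The risers were NAP (AT1G69490, 1.65 ± 0.16), the asparagine synthetase gene DIN6 (AT3G47340, 1.53 ± 0.19) and NAC2 (AT5G39610, 1.42 ± 0.20).

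Of 22729 genes 282 changed in Yb roots, 198 up and 84 down, all with groups that did not overlap (20.2% of all tested genes, where chance gives 10%), and 117 by at least a doubling or halving. The count changed when a single library was left out. It was 8 without Yb 1, 36 without Yb 2, 38 without control 3, 58 without control 2 and 179 without control 1. Without Yb 3, the library beside the controls on the first component, it was 1140. It was 1026 with DESeq2 and 1281 with library weights, and 149 with the 6 compared libraries alone. The balance of directions moved with it: 498 up and 642 down without Yb 3, 708 and 573 with library weights, 599 and 427 with DESeq2, and 35 and 3 without control 3. Of 23 named genes called, IMA1 and NAP kept their call without each library in turn. Calls were lost without Yb 1 (21), Yb 2 (19), Yb 3 (1), control 1 (15), control 2 (18) and control 3 (16).

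Genes that rose in Yb roots include XTH11 (AT3G48580), at least 5.8-fold higher than the controls at 0, SCRL26 (AT4G22105), a small cysteine-rich protein gene at least 2.73-fold higher, and AT1G51020 (4.11 ± 0.72). HO4 (AT1G58300), a heme oxygenase gene, went from 9.767 ± 6.28 to 100.7 ± 57.3 (adjusted p = 0.0336), while AT1G17600 was at least 1.47-fold higher and AT2G32200 rose by 3.15 ± 0.62. Genes that fell include DIN11 (AT3G49620, -2.24 ± 0.38), AT4G33120 (-1.75 ± 0.33), scpl5 (AT1G73290, -1.33 ± 0.26), AT1G33870 (-1.31 ± 0.25) and AT3G13840 (-1.26 ± 0.23). The largest fitted fall was that of the mitochondrial gene ATMG00030, -3.5 ± 0.70 (adjusted p = 0.0446). Mitochondrial reads made up 0.065% and 0.055% of control libraries 1 and 3 against 0.012% or less in every other root library. In other lists the chaperone gene BIP3 (AT1G09080) rose by 2.21 ± 0.42, the kinase gene FRK1 (AT2G19190) by 1.77 ± 0.30, ACS7 (AT4G26200) by 2.13 ± 0.38 and HAI1 (AT5G59220) by 0.87 ± 0.17. COR47 (AT1G20440), a dehydrin gene, fell by 0.55 ± 0.09.

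A further 4 lists were called upward in Yb roots. The phosphate list had a median of 0.63 with 0 of 27 members past the test (0 adjusted over the list alone). It had adjusted p = 0.00112, and adjusted p = 0.704 with an estimated correlation. SPX1 (AT5G20150) and PHT1;4 (AT2G38940) had 0.56 ± 0.37 and 0.91 ± 0.43. All 13 cell cycle genes had positive values, none past the test (0 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.00397, and adjusted p = 0.521 with an estimated correlation). The auxin list had 2 members up adjusted over the list alone (adjusted p = 0.0158, and adjusted p = 0.342 with an estimated correlation). The heat shock list had 1 up, BIP3 (adjusted p = 0.0311, and adjusted p = 0.704 with an estimated correlation). The 16 root hair genes had a median of -0.91 with 0 past the test (0 adjusted over the list alone; adjusted p = 0.0515, and 0.704 with an estimated correlation). It had adjusted p = 0.00432 without Yb 3, 0.439 without Yb 2 and 0.157 without control 1, from 0.0598 to 0.0847 without the others, 0.0413 with quantile normalization and 0.0113 with the replicate block. Its library medians were -1.14, -1.76 and 0.22 in Yb 1, Yb 2 and Yb 3. Without control 3, the phosphate, auxin and iron storage lists each had adjusted p = 0.0607 and the heat list 0.185. Without control 2 the phosphate list had 0.0751, and without Yb 3 the heat list had 0.379. ALMT1 (AT1G08430), ZIP9 (AT4G33020) and APR3 (AT4G21990) had 0.27 ± 0.48, -0.81 ± 0.31 and 0.10 ± 0.12, not past the test.

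The direct comparison of La with Yb in roots asked where the elements differed at the same dose and time. The glutathione transferase GSTU19 (AT1G78380) was higher with La by 0.67 ± 0.10 (adjusted p = 0.0107) and FRO3 (AT1G23020) by 0.75 ± 0.11 (adjusted p = 0.0103). Also higher were IRT1 (AT4G19690) by 0.98 ± 0.23 (adjusted p = 0.0427) and ZIP2 (AT5G59520) by 1.96 ± 0.24 (adjusted p = 0.00794). Of 22729 genes 1466 differed, 600 higher and 866 lower with La, all with groups that did not overlap (28.7% of all tested genes, where chance gives 10%). The count was 272 without La 3, 338 without La 2, 540 without Yb 1 and 592 without Yb 3, 2507 with DESeq2, 2744 with library weights and 508 with the 6 compared libraries alone. The excess of lower genes turned around with the 6 compared libraries, where 270 were higher and 238 lower. It was smaller but kept its direction without Yb 1 (265 higher and 275 lower), La 3 (127 and 145) or Yb 3 (271 and 321).

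Of the 16 root hair genes 1 was lower with La past the test, RHD6 (AT1G66470, -1.76 ± 0.41), and 15 did not pass (0 up and 12 down adjusted over the list alone). All 16 were negative, with a median of -2.99 (adjusted p = 6.02e-09, and adjusted p = 0.359 with an estimated correlation). Of 18 oxidative stress genes 5 were higher and 13 did not pass (10 up and 0 down adjusted over the list alone), among them ZAT12 (AT5G59820, 0.84 ± 0.14) and GSTU24 (AT1G17170, 0.93 ± 0.16). The list had adjusted p = 0.00013, and adjusted p = 0.182 with an estimated correlation. Of 27 iron deficiency genes 3 were higher and 24 did not pass (3 up and 0 down adjusted over the list alone). Beside FRO3 and IRT1 these include BTSL1 (AT1G74770, 0.54 ± 0.14), and the list had adjusted p = 0.000951, and adjusted p = 0.359 with an estimated correlation. Of 17 immunity genes 3 were lower and 14 did not pass (0 up and 7 down adjusted over the list alone). The list median was -0.63 (adjusted p = 0.000951, and adjusted p = 0.359 with an estimated correlation). The lower members were SARD1 (AT1G73805, -1.26 ± 0.22), WRKY53 (AT4G23810, -0.85 ± 0.19) and EDS5 (AT4G39030, -0.73 ± 0.18), which act in salicylic acid signalling. Of 11 senescence genes NAC2 (AT5G39610, 1.37 ± 0.20) and NYC1 (AT4G13250, 1.31 ± 0.27) were higher and 9 did not pass (3 up and 0 down adjusted over the list alone). That list had adjusted p = 0.0027, and adjusted p = 0.359 with an estimated correlation.

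The abscisic acid list was higher with La with 0 members past the test (3 up and 0 down adjusted over the list alone; median 0.97, adjusted p = 0.000202, and adjusted p = 0.359 with an estimated correlation). The cell cycle list was lower (0 up and 4 down adjusted over the list alone; median -0.27, adjusted p = 0.0027, and adjusted p = 0.377 with an estimated correlation). The aluminium list (2 up adjusted over the list alone, adjusted p = 0.0367, and adjusted p = 0.359 with an estimated correlation) and the ethylene list (0 adjusted over the list alone, adjusted p = 0.0455, and adjusted p = 0.581 with an estimated correlation) were higher. Both had adjusted p = 0.0538 under quantile normalization in roots. Without La 1 the aluminium and cell cycle lists reached adjusted p = 0.05 and the ethylene list 0.0931. The ethylene list had 0.182 without La 3, 0.193 without Yb 2 and 0.0933 without Yb 3. In the cell wall list XTH24 (AT4G30270) was higher by 1.70 ± 0.26, EXPB1 (AT2G20750) was lower (-2.51 ± 0.47) and XTH4 (AT2G06850) was lower (-0.47 ± 0.12). In the zinc list ZIP5 (AT1G05300, adjusted p = 0.0465) was lower and ZIP10 (AT1G31260), at 0 with La, was at least 6.79-fold lower. That bound rested on library Yb 3 and was 1.86-fold without it.

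The genes with the largest differences between La and Yb in roots were AT4G08550 (3.88 ± 0.77), XTH11 (AT3G48580, 3.35 ± 0.81), MYB62 (AT1G68320, 3.17 ± 0.60), AT4G17580 (3.09 ± 0.77) and MBP2 (AT1G52030, 3.05 ± 0.69). AT2G12190, which has a near-identical copy, was at 0 with Yb and at least 1.53-fold higher with La; without La 2 its La mean lay under the floor of 3 counts, 0.678 of it, and no fold can be given. Lower with La were AT5G46900 (-7.47 ± 1.21), AT4G19750 (-6.57 ± 1.43), AT5G46890 (-6.39 ± 1.04), AT4G12510 (-5.69 ± 1.13), AT1G50050 (-5.29 ± 0.92) and AT3G18450 (-5.23 ± 1.04). BHLH38, FER1, SPX1, PHT1;4, ALMT1, ZIP9 and APR3 did not pass, with adjusted p from 0.132 to 0.961. The 95% interval of the difference was 0.22 to 2.11 for BHLH38, -0.62 to 0.13 for FER1 and -0.82 to 0.91 for SPX1, so these do not show equal responses. Of 29 named genes called, FRO3, GSTU19, NAC2, ZAT12 and ZIP2 kept their call without each library in turn. Calls were lost without La 1 (7), La 2 (18), La 3 (22), Yb 1 (17), Yb 2 (6) and Yb 3 (13).

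Both elements changed 238 root genes in the same direction, 179 up and 59 down, and 1 gene in opposite directions. Independent lists of these sizes would share 18.63 genes up and 7.986 down, but the shared controls make the real lists dependent. The 10 simulations with unchanged treated groups and the same controls shared 0. With no change few genes pass either test, so this does not say how many the real La and Yb changes would share by chance. Across genes, which are not independent replicates, the log2 fold changes of La and Yb correlated with r = 0.674, and their covariance was 0.343. In 100 simulations in which shared controls alone related them the means were 0.5 and 0.0689. Noise was drawn there for each gene on its own, without shifts that the genes of a library share. The shared count was 8 without Yb 1, 36 without Yb 2, 37 without control 3, 50 without control 2, 143 without La 3 and 1001 without Yb 3.

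**Figure D3:**
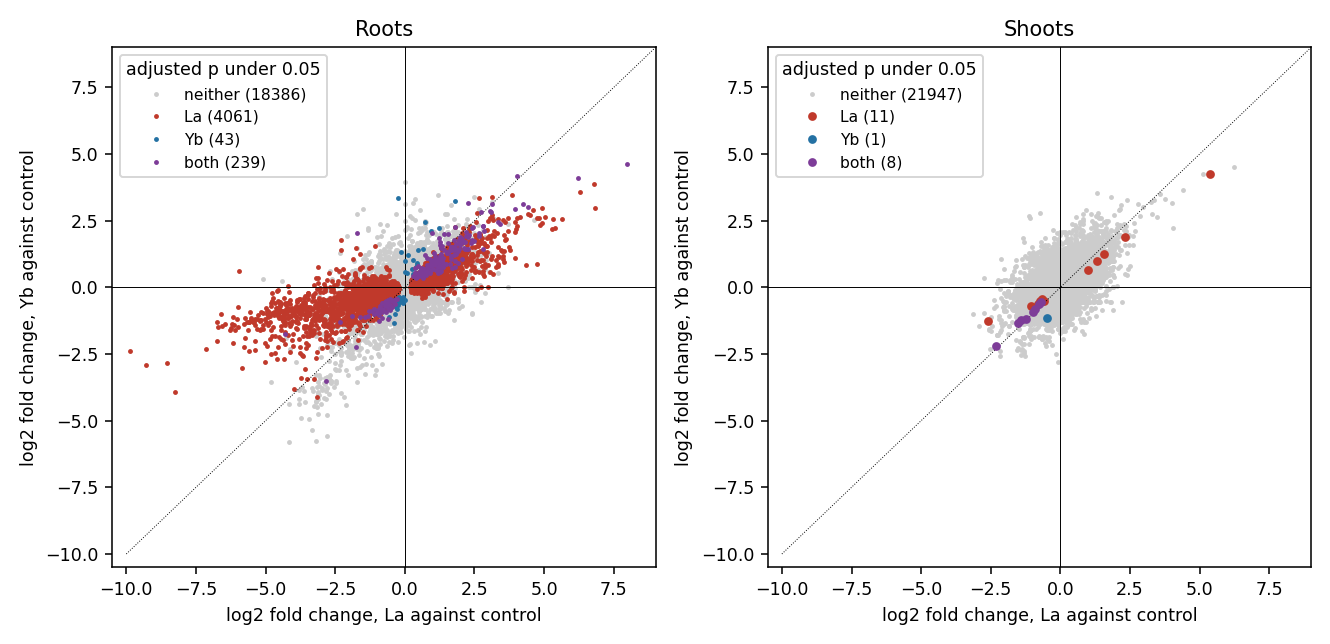
Each point is a gene, with its log2 fold change against control for La on the horizontal axis and for Yb on the vertical axis, in roots and in shoots, coloured by which contrasts it passed. In roots 4061 genes passed with La alone, 43 with Yb alone and 239 with both. In shoots the numbers were 11, 1 and 8.

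In shoots few single genes changed with La. Among them were 4 members of the iron lists: BHLH38 (AT3G56970) and OPT3 (AT4G16370) of the iron deficiency list rose, while FER4 (AT2G40300), a ferritin, and NEET (AT5G51720), an iron-sulfur protein of plastids and mitochondria, fell. OPT3 went from 970.5 ± 136 to 2432 ± 503, by 1.31 ± 0.15 (adjusted p = 0.0188), and BHLH38 from 0.6998 ± 1.21 to 42.76 ± 25.6 (adjusted p = 0.0359). NEET went from 967.5 ± 128 to 358 ± 34.5, by -1.43 ± 0.12 (adjusted p = 0.00117), and FER4 from 676.8 ± 198 to 228.6 ± 5.46, by -1.52 ± 0.17 (adjusted p = 0.0141). Of the 22 measured iron deficiency genes 2 rose and 20 did not pass. Adjusted over the list alone 14 rose and 0 fell, with a median of 1.34 (adjusted p = 4.76e-26, and adjusted p = 0.126 with an estimated correlation). Of 10 iron storage genes 2 fell and 8 did not pass (0 up and 5 down adjusted over the list alone; median -0.65, adjusted p = 5.7e-07, and adjusted p = 0.203 with an estimated correlation). FER1 (AT5G01600) had -2.18 ± 0.73 (adjusted p = 0.524), with control libraries at 1016, 2684 and 8429 and La libraries between 461.1 and 872.9.

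**Figure D4:**
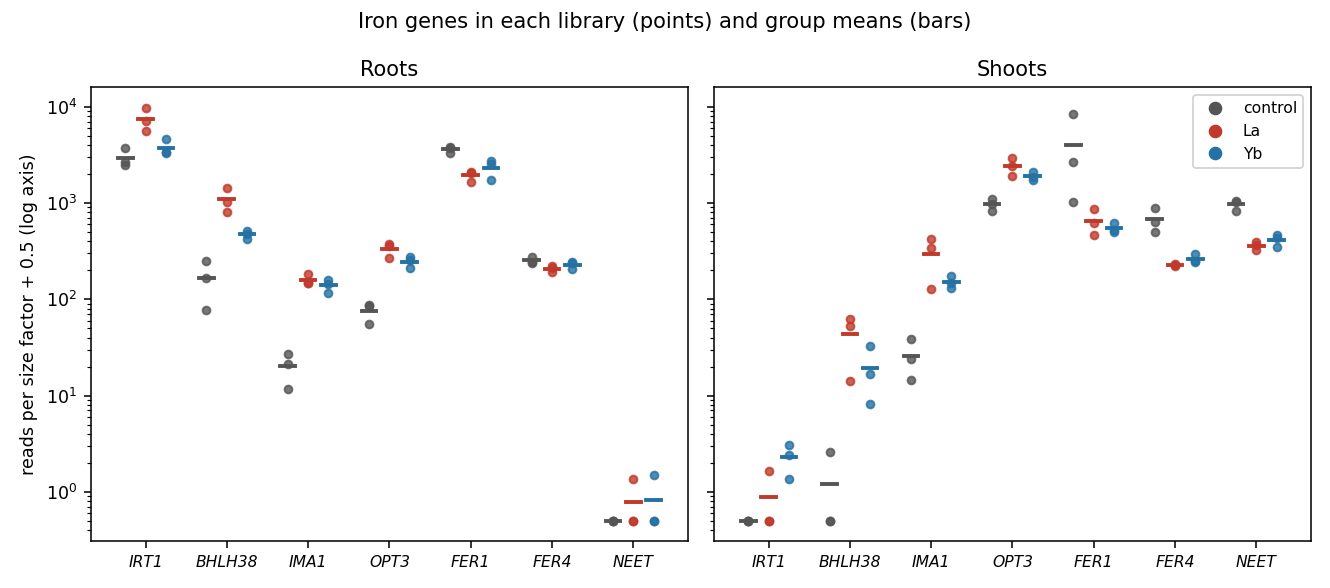
Reads per size factor plus 0.5, on a log axis, of 7 iron genes in roots and shoots; points are libraries and bars mark group means. In shoots NEET lies at 967.5 in the controls, 358 with La and 414.2 with Yb, and IMA1 at 25.17, 297.5 and 150.4.

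Of 21967 genes tested in shoots 19 changed with La, 5 up and 14 down (12.4% of all tested genes had groups that did not overlap, where chance gives 10%). The other rises were AT2G30760 (2.33 ± 0.35), which lies opposite the iron gene IMA3, AT5G50360 (1.58 ± 0.26) and AT1G73040 (0.98 ± 0.15). The other large falls were AT3G62950 (-2.61 ± 0.39), AT3G49160 (-2.31 ± 0.32), the MYB-like gene MEE3 (AT2G21650, -1.25 ± 0.18) and AT5G59080 (-1.06 ± 0.17). The count was 3 without La 1, 4 without La 2, 37 without control 2, 42 without La 3 and 100 without control 3, and 49 with the replicate block, 121 with DESeq2 and 7 with the 6 compared libraries alone. Directions moved too: 16 were up and 16 down without robust moderation, 22 and 20 without La 3, 39 and 61 without control 3, 50 and 71 with DESeq2, and 0 and 7 with the 6 compared libraries. Of 11 named genes called, NEET kept its call without each library in turn. Calls were lost without La 1 (10), La 2 (9), La 3 (3), control 1 (5), control 2 (3) and control 3 (1).

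Of the panel, SPX1 (AT5G20150), PHT1;4 (AT2G38940), ALMT1 (AT1G08430), ZIP9 (AT4G33020) and APR3 (AT4G21990) had -0.53 ± 0.14, -0.20 ± 0.32, 0.85 ± 0.43, -0.54 ± 0.86 and -0.15 ± 0.20 in La shoots, none past the test. IRT1 (AT4G19690) was at 0 in the shoot controls and at 0.3799 ± 0.658 with La (adjusted p = 0.916), under the floor of 3 counts, so no fold is given. The 25 phosphate genes, 0 of them past the test (0 up and 2 down adjusted over the list alone), had a median of -0.31 (adjusted p = 9.58e-07, and adjusted p = 0.669 with an estimated correlation). Library medians of this list were 0.15, -0.48 and 0.29 in the controls and -0.15, -0.32 and -0.54 with La, so control 2 lay within the La range. The 15 anthocyanin and flavonoid genes (0 adjusted over the list alone) had a median of 0.56 (adjusted p = 1.27e-05, and adjusted p = 0.669 with an estimated correlation). Here the library medians were 0.03, -0.68 and 0.63 in the controls and 0.51, 0.84 and 0.39 with La, so control 3 lay within the La range. The abscisic acid genes (0 adjusted over the list alone) had 0.19 (adjusted p = 0.000732, and adjusted p = 0.463 with an estimated correlation). Their library medians were -0.11, 0.09 and 0.11 in the controls and 0.23, 0.06 and 0.12 with La, so La 2 lay within the control range. Also called upward were the heat shock list (1 up adjusted over the list alone, adjusted p = 0.0133, and adjusted p = 0.669 with an estimated correlation) and the zinc list (1 up adjusted over the list alone, adjusted p = 0.0464, and adjusted p = 0.463 with an estimated correlation). Without control 2 the anthocyanin, zinc and heat lists had adjusted p = 0.117, 0.162 and 0.18 in shoots. Without control 1 zinc and heat had 0.0863 and 0.0713, without La 3 they had 0.052 and 0.0505, and without La 2 zinc had 0.345.

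In shoots exposed to Yb, 9 of 21967 genes passed in the reported fit, 0 higher and 9 lower, but other settings gave rises. There were 12 rises among 34 genes with the replicate block, 8 of 13 with the 6 compared libraries, 6 of 15 without robust moderation, 2 of 14 with library weights, 1 of 10 with edgeR and 50 of 102 with DESeq2. Rises were 108 of 166 without control 3, 12 of 21 without control 1, 2 of 6 without control 2 and 1 of 6 without Yb 1 or Yb 3. At an unadjusted p below 0.05 there were 1855 genes. NEET (AT5G51720) fell by 1.22 ± 0.12 (adjusted p = 0.0052), FER4 (AT2G40300) by 1.33 ± 0.17 (adjusted p = 0.0373), AT3G43670 by 0.94 ± 0.11 (adjusted p = 0.0052). MEE3 (AT2G21650) fell by 1.2 ± 0.18, AT3G49160 by 2.22 ± 0.32 and the thionin gene AT1G66100, which overlaps another gene on its strand, by 1.13 ± 0.14. The share of all tested genes with no overlap was 14.1%, where chance gives 10%. The count was 1 without Yb 2. In Yb shoots 1 gene of 6 was higher with equal library totals and 1 of 10 with quantile normalization. Of 6 named genes called, NEET kept its call without each library in turn. Calls were lost without Yb 1 (3), Yb 2 (5), Yb 3 (3), control 1 (1) and control 2 (3).

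In Yb shoots the lists with the lowest p were iron deficiency and immunity. The 22 iron deficiency genes had a median of 1.00, with 0 past the test singly and 16 up and 0 down adjusted over the list alone. It had adjusted p = 6.2e-21, and adjusted p = 0.136 with an estimated correlation. BHLH38 (AT3G56970) had 4.26 ± 0.78 (adjusted p = 0.145) and OPT3 (AT4G16370) 0.98 ± 0.15 (adjusted p = 0.106). The shoot controls of BHLH38 lay on average under the floor of 3 counts, so its fitted size depends on the pseudocount. Of the 10 iron storage genes 2 fell and 8 did not pass (0 up and 5 down adjusted over the list alone; median -0.93, adjusted p = 1.55e-08, and adjusted p = 0.136 with an estimated correlation). FER1 (AT5G01600) had -2.38 ± 0.73 (adjusted p = 0.487). All 18 immunity genes were positive, with a median of 0.75 and 0 past the test (3 up and 0 down adjusted over the list alone; adjusted p = 2.53e-12, and adjusted p = 0.171 with an estimated correlation). The 16 calcium signalling genes had a median of 0.55 (0 adjusted over the list alone, adjusted p = 6.35e-06, and adjusted p = 0.368 with an estimated correlation). Library medians of the calcium list were -0.04, -0.45 and 0.43 in the controls and 0.98, 0.11 and 0.49 with Yb, so control 3 lay above Yb 2. The 14 zinc genes had 0.16 (3 up adjusted over the list alone, adjusted p = 0.00263, and adjusted p = 0.19 with an estimated correlation).

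The other calls in Yb shoots were upward for the sulfate, senescence, jasmonate, oxidative stress, heat, anthocyanin and ethylene lists (adjusted p from 0.000731 to 0.0252, and adjusted p from 0.362 to 0.508 with an estimated correlation). They were downward for the cell wall list (0.0143, and adjusted p = 0.368 with an estimated correlation) and the phosphate list (0.0386, and adjusted p = 0.623 with an estimated correlation), with 0 members past the test over all genes. Adjusted over the list alone, 4 oxidative stress genes were up and 3 down, 1 gene each was up in the sulfate, senescence and ethylene lists, and 0 passed in the others. Each was also lost without at least 1 library. Without control 2 in shoots the sulfate, senescence, oxidative, heat, ethylene and cell wall lists had adjusted p = 0.0763, 0.108, 0.119, 0.156, 0.233 and 0.0511, and the jasmonate and anthocyanin lists 0.644, the latter turned downward. Without control 1 jasmonate and heat had 0.0821, cell wall 0.127 and phosphate 0.442; without control 3 phosphate had 0.635, turned upward. Without Yb 1 jasmonate, ethylene and anthocyanin had 0.811, 0.13 and 0.478, without Yb 2 phosphate and cell wall 0.338 and 0.237, and without Yb 3 phosphate and heat 0.0814 and 0.161. With equal library totals the jasmonate, ethylene, oxidative, heat and anthocyanin lists had 0.0516, 0.0516, 0.0516, 0.0519 and 0.0634, and with quantile normalization the phosphate list 0.114. SPX1 (AT5G20150), PHT1;4 (AT2G38940), ALMT1 (AT1G08430), ZIP9 (AT4G33020) and APR3 (AT4G21990) had -0.18 ± 0.14, 0 ± 0.32, 0.76 ± 0.43, -0.63 ± 0.86 and 0.39 ± 0.20, none past the test. IRT1 (AT4G19690) was at 0 in the shoot controls and at 1.79 ± 0.859 with Yb (adjusted p = 0.528), under the floor of 3 counts, so no fold is given.

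Between La and Yb, 2 shoot genes of 21967 passed: AT2G44940 was higher with La (0.76 ± 0.10, adjusted p = 0.0481) and AT3G06070 lower (-1.05 ± 0.11, adjusted p = 0.00611). The share of all tested genes with no overlap was 14%, where chance gives 10%. Without La 1, La 2 or Yb 3 both calls were lost, and without La 3, Yb 1 or Yb 2 1 of them. The count was 71 with the 6 compared libraries alone, 83 with DESeq2, 32 with library weights and 30 with the replicate block, and in these 10, 13, 5 and 2 were higher with La. All 18 immunity genes were lower with La than with Yb, with a median of -0.83 and 0 past the test (0 up and 7 down adjusted over the list alone). The list had adjusted p = 4.5e-15, and adjusted p = 0.32 with an estimated correlation. WRKY53 (AT4G23810) had -2.01 ± 0.54 (adjusted p = 0.611). Also lower were the calcium list (0 adjusted over the list alone, adjusted p = 6.82e-06, and adjusted p = 0.631 with an estimated correlation) and the sulfate list (2 down adjusted over the list alone, adjusted p = 2.57e-05, and adjusted p = 0.358 with an estimated correlation). These 3 calls held without each library in turn but not with an estimated correlation. The panel genes IRT1, BHLH38, FER1, SPX1, PHT1;4, ALMT1, ZIP9 and APR3 did not pass, with adjusted p from 0.693 to 0.996.

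A further 4 lists were lower with La than with Yb in shoots, phosphate (adjusted p = 0.00144), jasmonate (0.00269), auxin (0.02) and oxidative stress (0.0402), each with adjusted p = 0.631 with an estimated correlation. The higher lists were iron deficiency (0.00493), abscisic acid (0.00592), copper (0.0396), anthocyanin (0.0433) and photosynthesis (0.0448), with adjusted p from 0.358 to 0.655 with an estimated correlation. Adjusted over the list alone, 2 auxin genes were down, 1 abscisic acid gene was up and 0 passed in the others. Without La 1 the iron, copper, abscisic acid and photosynthesis lists had adjusted p = 0.142, 0.152, 0.0546 and 0.264 in shoots. Without La 2 iron, copper, oxidative, anthocyanin and photosynthesis had 0.0847, 0.0912, 0.12, 0.468 and 0.0997, and without La 3 phosphate, oxidative, jasmonate, auxin and abscisic acid had 0.162, 0.185, 0.0743, 0.0743 and 0.0743. Without Yb 1 oxidative and jasmonate had 0.0821 and 0.534, and without Yb 2 copper, auxin, anthocyanin and photosynthesis 0.0554, 0.176, 0.176 and 0.0596. Without Yb 3 copper, oxidative, abscisic acid, anthocyanin and photosynthesis had 0.0715, 0.123, 0.133, 0.673 and 0.399. With the replicate block copper had 0.0507, and with quantile normalization abscisic acid, anthocyanin and copper had 0.0638 and photosynthesis 0.963.

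In shoots 8 genes fell with both elements and 0 rose with both. They were NEET, FER4, the ferredoxin gene FED A (AT1G60950), the stromal ascorbate peroxidase gene SAPX (AT4G08390), ABCI8 (AT4G04770), which serves the assembly of iron-sulfur clusters in plastids, MEE3, AT3G43670 and AT3G49160. FED A fell by 0.90 ± 0.09 with La and 0.81 ± 0.09 with Yb, and SAPX by 0.68 ± 0.09 and 0.55 ± 0.09. Independent lists would share 0.006 falling genes, but the shared controls make the real lists dependent. The highest of 10 simulations with no change and the same controls was 1, where few genes can pass either test. Across genes the effects correlated with r = 0.534, and their covariance was 0.09. In 100 simulations with the same controls and noise drawn for each gene on its own the means were 0.499 and 0.0617. The shared count was 1 without Yb 2, 3 without La 1, 4 without La 2, Yb 1 or Yb 3, 5 without control 2, 19 without La 3 and 58 without control 3, and it was 22 with the replicate block.

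The La effect differed between roots and shoots in 1440 of 20981 genes tested in both tissues, 806 with a higher effect in roots and 634 with a lower one, and the Yb effect in 65, 50 and 15. Genes of the senescence list differed with La: NYC1 (AT4G13250) had 2.63 in roots and -0.56 in shoots (difference 3.18 ± 0.34, adjusted p = 0.000218), and NAP (AT1G69490) 2.02 and -0.59 (difference 2.62 ± 0.46, adjusted p = 0.00416). The ferritin FER4 (AT2G40300) had -0.28 in roots and -1.52 in shoots with La (difference 1.25 ± 0.21, adjusted p = 0.0028) and -0.14 and -1.33 with Yb (difference 1.18 ± 0.21, adjusted p = 0.0239). The phosphate list had a higher effect in roots with both elements, medians of 0.65 in roots and -0.31 in shoots with La (adjusted p = 0.000209, and adjusted p = 0.748 with an estimated correlation). With Yb they were 0.63 and -0.14 (adjusted p = 0.000197, and adjusted p = 0.768 with an estimated correlation). With each library left out the highest adjusted p was 0.00626 for La and 0.0457 for Yb, both without root control 2. The root controls themselves stood apart in this list (0.9, -0.58 and -0.35), as did the shoot controls (0.15, -0.48 and 0.29). The call of the phosphate list in roots alone was lost in 4 of 6 such fits with La and 2 of 6 with Yb. With La the senescence (adjusted p = 0.000688), abscisic acid (0.000339) and oxidative stress (0.0112) lists were also higher in roots, each with adjusted p = 0.697 with an estimated correlation. The oxidative stress list had 0.0631 without shoot control 3. The iron deficiency list did not differ past the test with La (adjusted p = 0.249, and 0.00289 without shoot library La 3) and was lower in roots with Yb (adjusted p = 0.0292, and adjusted p = 0.768 with an estimated correlation). With Yb the cell cycle list was also higher in roots (medians of 0.18 and -0.08, adjusted p = 0.00146, and adjusted p = 0.719 with an estimated correlation). The calcium signalling list was lower in roots with Yb (medians of 0.11 and 0.55, adjusted p = 0.0498, and adjusted p = 0.768 with an estimated correlation). The iron difference with Yb had adjusted p = 0.0667, 0.0712 and 0.0753 without root control 1, control 2 or Yb 2, and 0.103 and 0.118 without shoot control 3 or Yb 2. The calcium difference had 0.209, 0.102 and 0.0685 without root control 2, Yb 2 or Yb 3, and 0.117, 0.443 and 0.195 without shoot control 1, control 2 or Yb 1. The La count was 871 without root library La 2 and 932 without shoot library La 2, and the Yb count 369 without root library Yb 3. Without root library control 1 or Yb 1 the Yb count was 111 or 23, and without shoot library control 2, Yb 1, Yb 2 or Yb 3 it was 26, 31, 37 or 14.

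Markers of other tissues were measured beside these changes. In roots the 22 photosynthesis genes, which mark green tissue, had medians of 0.50 with La (adjusted p = 0.168), 0.20 with Yb (0.593) and 0.34 for La against Yb (0.309). In each, 0 passed the test and 0 adjusted over the list alone. With single libraries left out the list was called upward with La without control 1 (0.0252), with Yb without Yb 3 (0.0242) and for La against Yb without Yb 1 (0.00271). In shoots all 22 photosynthesis genes were negative, with medians of -0.10 with La (adjusted p = 0.0179, and adjusted p = 0.68 with an estimated correlation) and -0.20 with Yb (adjusted p = 7.66e-06, and adjusted p = 0.368 with an estimated correlation). Of these 0 passed singly or adjusted over the list alone. Without control 1 or La 3 the La value was 0.69 or 0.165, and with quantile normalization the La and Yb values were 0.51 and 0.415. Only 4 root hair genes were measured in shoots, too few for the test of lists, and 0 of them passed. The 13 Casparian strip and suberin genes measured in shoots had 0 past the test (0 adjusted over the list alone) and a median of 0.37 with La (adjusted p = 0.0328, and adjusted p = 0.293 with an estimated correlation). That call was lost without control 3 (0.111) or La 3 (0.0946), with equal library totals (0.111) and with quantile normalization (0.0767), and with Yb the list had adjusted p = 0.121 (0.0333 without Yb 3). Floral genes were not called in shoots (adjusted p = 0.478 with La and 0.317 with Yb, 1 member up adjusted over the list alone in each). Nor were they called in roots (0.524 and 0.855), where SOC1 (AT2G45660) fell by 0.53 ± 0.09 with La. Circadian clock genes were not called in shoots (0.475 and 0.404) or in roots (0.524 and 0.443), where GI (AT1G22770) rose by 0.38 ± 0.09 with La. For La against Yb in roots the clock list had adjusted p = 0.0801. It was called upward in 2 of 6 fits with a library left out (lowest adjusted p 0.0368).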

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

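The test of this part and the splits were set before the data were examined, whereas the bound without a library and the tally of splits that kept the root groups were chosen only after the results had been seen. A difference between the effects in roots and shoots, tested as an interaction, singled out the results below. With La, 1440 of 20981 genes differed, and with Yb 65. Of the genes named here with reads in each group, the La effect was higher in roots for AT4G05540 (7.08, adjusted p = 0.0161), 5PTASE11 (6.4, 0.00521), NYC1 (3.18, 0.000218), NAP (2.62, 0.00416), NAC2 (2.06, 0.0078), AT3G49160 (2.03, 0.00646), MEE3 (1.87, 0.00754), FER4 (1.25, 0.0028), HAI1 (1.21, 0.0337) and AT3G43670 (0.82, 0.0106), each given as the log2 fold change in roots minus that in shoots. It was lower in roots for RSL2 (-4.28, 0.0165) and DIN11 (-2.48, 0.017). With Yb it was higher in roots for HO4 (4.38, 0.0288), MEE3 (2.16, 0.0226), AT3G49160 (1.98, 0.0429), FER4 (1.18, 0.0239) and AT3G43670 (0.89, 0.0385). FER4 overlaps another gene on its strand. The root controls of AT4G05540 and 5PTASE11 lay on average under the floor of 3 counts, so the sizes of their differences depend on the pseudocount as well. For 3 further genes the fitted difference rests on a root group at 0, so it depends on the pseudocount and gives no size: XTH11 (8.82, 0.00118 with La) and AT1G17600 (1.87, 0.0361 with La and 3.13, 0.0141 with Yb), at 0 in the root controls, and MTP2 (-5.14, 0.0251 with La), at 0 in La roots. In roots XTH11 was at least 41.7-fold higher with La, AT1G17600 at least 1.47-fold higher with Yb, and MTP2 at least 5.07-fold lower with La (2.78 without control 2). AT1G17600 in La roots lay under the floor of 3 counts, so no fold is given.

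Other splits of the libraries did not exclude chance for these counts. Of 100 splits 7 gave as many genes as the real La count of 1440, with a highest other count of 2807, and 5 gave as many as the real Yb count of 65, with a highest other count of 245. All 6 other splits with a count as high for La, and all 4 for Yb, kept the real groups of the root libraries and regrouped the shoot libraries. The high counts therefore follow the structure of the root samples, and they do not part a difference between tissues from a root effect set against regrouped shoots.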

How the results depend on the processing

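The tests added only after the data had been seen were edgeR, DESeq2, a minimum value of 10 for lists each left-out library and the 3 scalings, and for lower bounds and list differences between tissues each left-out library; the cause of the changes below was not tested. Changed genes in La roots were 1797 at a log2 fold change of at least 1, and 2588 to 3738 with single libraries left out. In Yb roots they were 1281 with library weights, 149 with the 6 compared libraries, 1026 with DESeq2, 117 at a log2 fold change of at least 1, and 8 to 1140 with libraries left out. For La against Yb in roots these were 2744, 508, 2507, 557 and 272 to 1485. In La shoots they were 32 without robust moderation, 7 with the 6 compared libraries, 49 with the replicate block, 121 with DESeq2, 10 at a log2 fold change of at least 1, and 3 to 100 with libraries left out. In Yb shoots they were 15 without robust moderation, 14 with library weights, 34 with the replicate block, 102 with DESeq2, 5 at a log2 fold change of at least 1, and 1 to 166 with libraries left out. For La against Yb in shoots they were 1 with a pseudocount of 0.1, no filter, a minimum value of 5 or 10, equal library totals or a log2 fold change of at least 1, 32 with library weights, 71 with the 6 compared libraries, 30 with the replicate block, 83 with DESeq2, and 0 to 2 with libraries left out. Genes changed by both elements were 8 to 1001 in roots and 1 to 58 in shoots with libraries left out, and 22 in shoots with the replicate block. Genes whose effect differed between tissues were 871 to 1528 for La and 14 to 369 for Yb with libraries left out. Rescaling by median ratios repeats the deposited scaling and tested nothing. Counts under the other settings stayed within 1.5 times the reported ones.

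With an estimated correlation 0 lists were called in every comparison, and with fry 10 in La roots, 2 in Yb roots, 2 for La against Yb in roots, 1 in La shoots, 2 in Yb shoots and 0 for La against Yb in shoots. With libraries left out the calls were 6 to 9, 3 to 10 and 8 to 10 in roots for La, Yb and La against Yb, and 6 to 13, 7 to 16 and 7 to 11 in shoots. Of 2899 values of named genes, 2492 kept their direction and side of the threshold, 372 lost it, 15 gained it and 20 changed direction, none of these past the threshold. The kept values include all those under rescaling by median ratios, which tested nothing. SPX1 for La against Yb in roots had -0.02 with quantile normalization, -0.08 with library weights and -0.11 to 0.25 with libraries left out. PHT1;4 in Yb shoots had -0.02 with quantile normalization, -0.09 with library weights, -0.06 with edgeR and with DESeq2, and -0.34 to 0.26 with libraries left out. With libraries left out ALMT1 had -0.09 to 0.8 in Yb roots, PHT1;4 -0.55 to 0.05 and ZIP9 -1.05 to 0.12 in La shoots, and FER1 -0.04 to 0.42, ALMT1 -0.28 to 0.31 and ZIP9 -0.53 to 0.75 for La against Yb in shoots. Whether replicate numbers pair the libraries was not settled. Within a tissue 8 of 18 and between tissues 6 of 9 correlated best with their own number, where chance gives 1 in 3. The r values were -0.24 to 0.38 and -0.02 to 0.16. The replicate block raised the changed genes in shoots from 19 to 49 with La, 9 to 34 with Yb and 2 to 30 between them. In roots it lowered them from 4300 to 3799, 282 to 239 and 1466 to 1159.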

Other observations

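The tests of the 3 patterns below, on iron, root hair and phosphate genes, were chosen only after the patterns had been seen, whereas the splits of libraries were set before the data were examined. Single genes passed in every list not called in La roots except photosynthesis. Since 4300 of 22729 tested genes changed in La roots, lists of this size would hold some by chance. Such counts alone do not show a response of the list. In the auxin list 5 of 18 genes rose and 2 fell (6 up and 3 down adjusted over the list alone, adjusted p = 0.113 for the list): GH3.3 (AT2G23170), which conjugates auxin, rose by 2.65 ± 0.60, and the auxin exporter PIN2 (AT5G57090) had -1.06 ± 0.24. In the copper list 4 of 11 rose (4 up and 0 down adjusted over the list alone, adjusted p = 0.0726 for the list, 0.0431 without control 2 and 0.0418 without La 3), among them the iron superoxide dismutase FSD1 (AT4G25100, 2.04 ± 0.41) and the copper transporter COPT2 (AT3G46900, 1.12 ± 0.31). In the sulfate list 4 of 15 rose and 3 fell (4 up and 4 down adjusted over the list alone, adjusted p = 0.552 for the list), with the transporter SULTR2;1 (AT5G10180) at 1.1 ± 0.19 and SULTR1;1 (AT4G08620) at -2.16 ± 0.49. In the aluminium list 3 of 12 rose (3 up and 0 down adjusted over the list alone, adjusted p = 0.157 for the list), among them the citrate exporter MATE (AT1G51340, 1.12 ± 0.18). In the calcium list 3 of 16 rose (4 up and 0 down adjusted over the list alone, adjusted p = 0.0726 for the list and 0.0207 without control 2). In the immunity list 2 of 17 rose and 4 fell (2 up and 5 down adjusted over the list alone, adjusted p = 0.156 for the list), and in the jasmonate list 2 of 18 rose and 1 fell (2 up and 1 down, 0.652). In the cell wall list 3 of 14 rose and 2 fell (3 up and 2 down, 0.759), and in the anthocyanin list 2 of 11 fell (0 up and 2 down, 0.646). The heat, cell cycle and clock lists had 1 gene up each (0, 0 and 1 up adjusted over the list alone). The nitrate and floral lists had 1 down each (1 and 1 down adjusted over the list alone).

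Of 12 genes often used as references, 1 rose and 3 fell in La roots (2 up and 3 down adjusted over the list alone, adjusted p = 0.841 for the list). ACT2 (AT3G18780) had 15710, 15450 and 14450 in the controls and 7934, 7011 and 7536 with La, a log2 fold change of -1.02 ± 0.20 (adjusted p = 0.00771), and TUB4 (AT5G44340) had -0.67 ± 0.11. With equal library totals and with quantile normalization the directions and calls of ACT2 and TUB4 held. ACT2 was at 9233 and 8437 in Yb 1 and Yb 2 and at 15620 in Yb 3. In roots Yb 3 also had 2042 reads of the phosphate transporter PHT1;3 (AT5G43360), against 35.49 or fewer in each other root library, and 1431 of ICS1 (AT1G74710), which makes salicylic acid, against 176.5 to 409.3.

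The iron deficiency list was called higher and the iron storage list lower with both elements in both tissues, and with an estimated correlation 0 of these calls held (adjusted p from 0.126 to 0.313). With fry, which compares with no other genes, iron deficiency had adjusted p = 0.00117 and 0.0178 in La and Yb roots and 0.0217 and 0.0251 in shoots. By fry the storage list passed in La roots (0.0115) and Yb shoots (0.0251) but not in Yb roots (0.102) or La shoots (0.05). Singly 0 of 22 iron deficiency genes passed in Yb shoots and 0 of 9 iron storage genes in Yb roots. The storage list had adjusted p = 0.0771 in La roots without La 2 and 0.0607 in Yb roots without control 3. In every library the list median of iron deficiency less that of iron storage, in which a scaling factor cancels, ran from 1.14 to 2.05 in exposed roots against -0.3 to 0.23 in control roots, a gap of 0.91, and the gap in shoots was 1.43. A factor between libraries cannot give this gap. Of 12 exposed libraries 12 lay above every control in the first list and below every control in the other, which argues against a change carried by a single library. The pattern may reflect a lower supply of iron to the plant or a disturbed sensing of it, and iron in the medium or the plants was not used here, so both remain open.

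Root hair genes were low in La roots (library medians of -2.98, -5.87 and -2.9) and at -1.14, -1.76 and 0.22 in Yb 1, Yb 2 and Yb 3. Yb 3 had an iron deficiency median of 0.84, above the highest control (0.2), which argues against an unexposed library with a wrong label. Fewer root tips in the La samples would lower cell cycle genes as well. Their median with La against control was -0.07 (quartiles -0.19 and 0.04, against -4.34 and -1.73 for root hair genes). For La against Yb it was -0.27 (adjusted p = 0.0027 for the list, and 0.377 with an estimated correlation). Part of that difference came from Yb, with a list median of 0.18 against control (adjusted p = 0.00397 for the list, and 0.521 with an estimated correlation). With La against control the list was not called (adjusted p = 0.669). This 1 list of 13 genes therefore shows no fall near that of the root hair genes, but it does not exclude fewer root tips. Fewer hair cells and less transcript per cell were not told apart here.

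Phosphate starvation genes of control root 1 had a median of 0.9, as high as in exposed libraries, against -0.58 and -0.35 in controls 2 and 3. Its iron deficiency median of 0.2 lay below every exposed root library (0.76 or higher), which argues against an exposed library with a wrong label. Control 3 shared its raised organellar reads but had a phosphate median of -0.35, which argues against the preparation those reads mark. Differences between plants or containers in phosphate status may remain, and were not tested.

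Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. For changed genes in La roots 1 split, the real one, gave a count as large (4300, highest other 0), in Yb roots 1 (282, highest other 0) and for La against Yb in roots 1 (1466, highest other 0). In La shoots it was 1 (19, highest other 3), in Yb shoots 2 (9, highest other 14) and for La against Yb in shoots 1 (2, highest other 0). For lists in roots 3 splits were as large for La (8, highest other 10), 5 for Yb (7, highest other 9) and 3 for La against Yb (9, highest other 10). For lists in shoots they were 5 for La (9, highest other 12), 1 for Yb (15, highest other 12) and 1 for La against Yb (12, highest other 8). The median count of lists over the other splits was 6 for La, 6 for Yb and 7 for La against Yb in roots. In shoots these medians were 7, 6 and 6. Groups that mixed the treatments thus also gave list calls, so the number of lists called does not by itself show a response.

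For genes changed by both elements in the same direction, 2 of 100 splits of the 9 libraries were as large in roots (238, highest other 764) and 2 of 100 in shoots (8, highest other 10). The splits treat all 9 libraries as alike, which an effect of 1 element alone would break. A low share therefore does not show that La and Yb share more genes than chance would give. The split with 764 took the 3 La libraries as its reference, so that both other groups differed from them, which points to the structure of the samples. In shoots the split with 10 took control 3, Yb 1 and Yb 3 as its reference.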
